A study of Homo sapiens with 6 samples.

How the data were processed

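The series holds RNA sequencing of A549 cells, a human lung carcinoma epithelial line, in 6 libraries. Per the labels, 3 libraries came from untreated cells and 3 from cells cocultured with the flagellate *Trichomonas tenax* at a multiplicity of infection of 1. Per the labels' protocols, RNA was extracted with a column kit and 1 µg of total RNA entered mRNA library preparation with the KAPA mRNA HyperPrep kit. The labels name no time point. They describe the replicates as separate samples and do not say whether these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

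The values are FPKM (fragments scaled by exon length and by the library's mapped total) per gene and library, as deposited by the authors in a single table of 58884 Ensembl gene identifiers. Per the submitters' processing notes, reads were handled with Trimmomatic, HISAT2 and DESeq2 against GRCh38, with no versions given. The read counter, its use of strand and the annotation release are not given in the sources used here. Of the identifiers, 58611 were found in GENCODE release 29, whose GRCh38 coordinates and biotypes are used below, and 273 were not.

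The FPKM values moved in whole-number steps, which gave the depth. Among 35339 genes above 0 in any library, the values of 35338 (99.997%) were whole multiples of a common step within 0.0001 reads, and for 30130 of them that step matched the gene's summed exon length within 2%. The denominators recovered in this way were whole numbers between 17726177 and 22095486, and the reads assigned to genes came to 16739055 to 20909814 per library. The labels name no molecular identifiers, so reads were not taken as counted molecules.

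Genes were tested if they reached 1 FPKM in at least 3 of the 6 libraries. The test was limma (3.58.1, in R 4.3.3) with an intensity trend on log2(FPKM + 1), two-sided, without a replicate block, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. A second count required an absolute log2 fold change of at least 1. The 38 gene lists were fixed before the data were examined, as were the design and most alternatives. Lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, again with an estimated correlation, and their members were also adjusted over the list alone.

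Named genes followed a rule fixed beforehand. It took the 10 largest log2 rises and falls and the 5 largest FPKM rises and falls among changed protein-coding genes with at least 5 FPKM in the higher group and no overlap between groups. It also took up to 4 members of each list with the smallest adjusted p, and members that went against their list. Genes named outside it are said to be chosen after their values were seen. A gene that the rule took is not reported here.

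The test was checked on simulated reads for 12585 genes drawn from the library means and depths, with 200 genes assigned a change. Every gene was given the same dispersion (0.000422), and no GC trend between libraries was simulated, so the shares may differ in the real libraries. The test called 26% of those simulated at a log2 change of 0.25, 75% at 0.5, 87.8% at 1 and 100% at 2, and 2.10% of its calls were false. Median estimates were 0.22, 0.45, 0.85 and 1.83 in that order. On the same reads limma-voom called 64%, 91.7%, 89.8% and 100%, and 8.20% of its calls were false. Pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom of 2.03 to 2.38), so no pair looked like the same library deposited more than once, which does not show that they came from separate cultures.

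Alternatives covered the pseudocount, the filter on low values, scaling between libraries, the variance model, a replicate block, a stricter threshold and leaving out each library. A correction for GC content, which removed each library's lowess trend (span 0.3) on the GC content of the longest transcript, and limma-voom on the recovered reads were added after the data were seen. Sharing of 50-base stretches with other annotated transcripts was counted for each named gene and each tested NF-kB list member. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.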

Results

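Gene expression was measured by mRNA sequencing in A549 human lung carcinoma cells that were untreated (3 libraries) or cocultured with *Trichomonas tenax*, a flagellate of the human oral cavity, at a multiplicity of infection of 1 (3 libraries). The comparison asks which A549 genes differ after coculture with the parasite. Depth, recovered from the steps of the FPKM values, was 20101505 to 22095486 mapped fragments in the untreated libraries and 17726177 to 20276411 in the cocultured ones. Between 12460 and 12665 genes reached 1 FPKM per library, and mitochondrial genes took 41.0% to 42.5% of the FPKM total. Correlations of log values were 0.988 to 0.991 within groups and 0.987 to 0.989 between groups.

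Cocultured cells held more mRNA of chemokine genes and less of *TFRC*, which encodes the transferrin receptor. *CCL20*, a chemokine that attracts lymphocytes and dendritic cells, rose from 3.50 ± 0.377 to 11.998 ± 0.499 FPKM (mean ± SD, n = 3 per group here and below). *CXCL1* and *CXCL8*, chemokines that attract neutrophils, rose from 38.9 ± 1.09 to 88.2 ± 4.67 and from 20.7 ± 1.54 to 46.7 ± 3.19 FPKM. *TFRC* fell from 65.2 ± 0.775 to 44.8 ± 0.137 FPKM. Of 12575 genes tested, 170 changed (limma, adjusted p under 0.05), 87 of them higher and 83 lower in coculture, with a median absolute log2 fold change of 0.26. On the log2(FPKM + 1) scale, which understates changes of low genes, 6 genes changed at least 2-fold. *CCL20*, *LCN2*, *CXCL1* and *CXCL8* were higher, and the small RNA genes *MIR1303* (log2 fold change -1.19) and *RNU6-882P* (-1.04), chosen after their values were seen, were lower. *MIR1303* was at 2.80 ± 1.15 and 0.617 ± 0.0414 FPKM and *RNU6-882P* at 3.89 ± 0.496 and 1.39 ± 0.373, untreated and cocultured. Both lay near the filter of 1 FPKM in coculture, in libraries prepared from mRNA, so these 2 falls are uncertain and may rest on few reads. Each of the 170 genes had 3 cocultured values beyond all 3 untreated ones, as did 26.8% of all tested genes, where chance gives 10%.

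*CCL20*, *CXCL1* and *CXCL8* were among 12 genes called whichever library was left out. The count of changed genes fell whichever library was left out, which also leaves fewer libraries to fit. It was 15, 19 and 26 without untreated replicates 1, 2 and 3, and 22, 22 and 21 without cocultured replicates 1, 2 and 3. It was also 30 without a filter on low values, 520 among genes with a mean of at least 5 FPKM, 29 without an intensity trend, 16 at an adjusted p of 0.01 and 1221 with limma-voom on recovered reads. The 12 genes called in all 6 fits without 1 library were *CCL20*, *CXCL1*, *CXCL2*, *CXCL5*, *CXCL8*, *CCL2*, *LCN2*, *SAT1*, *EREG*, *TFRC*, *EPAS1* and *CPLX2*. Fold changes also followed GC content across 10538 protein-coding genes (Spearman rho -0.36, across genes, which are not independent replicates). Median GC content was 41.4% for genes that rose, 54.1% for genes that fell and 47.7% for all tested protein-coding genes.

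**Figure D1:**
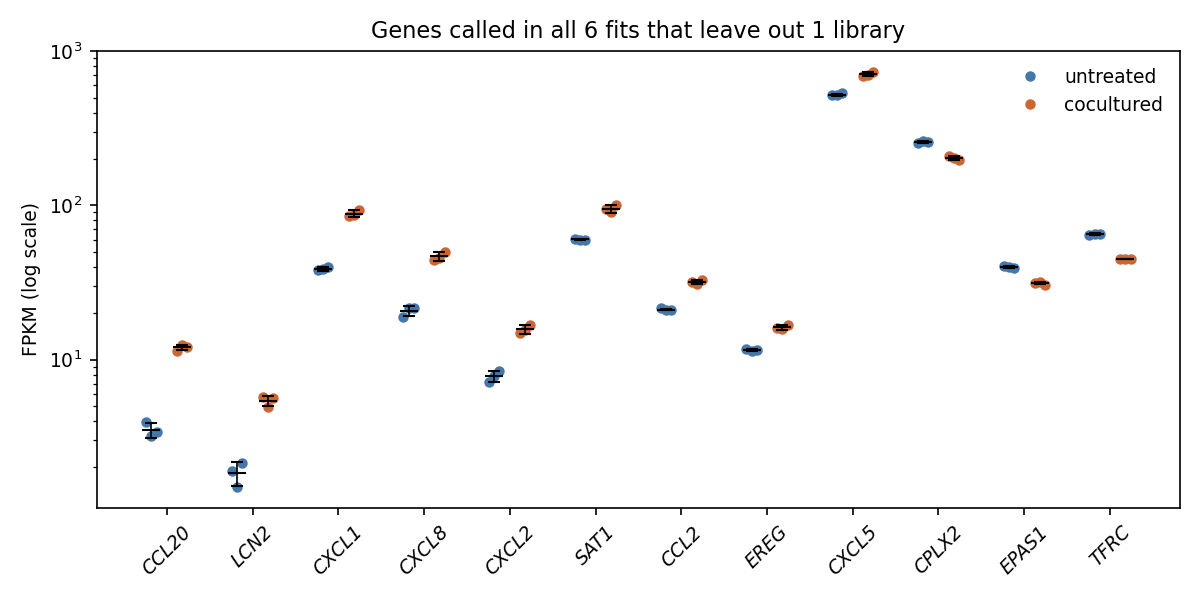
FPKM on a log axis of the 12 genes called in all 6 fits that leave out 1 library, with 3 untreated (blue) and 3 cocultured (orange) libraries as points and bars for mean ± SD. The groups do not overlap for any of the 12 genes, and CCL20 shows the widest separation, from 3.50 to 11.998 FPKM.

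Genes of the NF-kB and inflammatory cytokine list rose as a group. Of 23 tested members, 10 rose and none fell over all genes, and 17 were higher and 1 lower when adjusted over the list alone. The median log2 fold change was 0.28 and the camera adjusted p was 1.76e-15 (adjusted p = 0.239 with an estimated correlation). *CXCL5*, the most abundant member named, rose from 523 ± 8.18 to 712 ± 23.2 FPKM. *CXCL2* rose from 7.81 ± 0.623 to 15.7 ± 0.938, *CXCL3* from 5.86 ± 0.611 to 9.81 ± 0.481, and *CCL2*, which attracts monocytes, from 21.1 ± 0.296 to 32.0 ± 1.01 FPKM. *TNFAIP2*, *SOD2* and *BIRC3*, chosen after their values were seen, had log2 fold changes of 0.39, 0.28 and 0.36. The list's member lower when adjusted alone was *NFKB1*, which encodes a subunit of NF-kB itself, at 6.96 and 6.29 FPKM (log2 fold change -0.13, adjusted p = 0.181 over all genes). The inhibitor genes *NFKBIA* and *TNFAIP3*, also chosen after their values were seen, did not pass over all genes (0.15, adjusted p = 0.0907 and 0.34, adjusted p = 0.105).

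The log2 fold changes were 1.53 ± 0.065 (SE) for *CCL20* (adjusted p = 0.000276), 1.16 ± 0.041 for *CXCL1* (adjusted p = 0.000216) and 1.14 ± 0.065 for *CXCL8* (adjusted p = 0.00135). They were 0.92 ± 0.063 for *CXCL2* (adjusted p = 0.00265), 0.66 ± 0.070 for *CXCL3* (adjusted p = 0.0174) and 0.57 ± 0.031 for *CCL2* (adjusted p = 0.000969). The values cover the exons of each gene in GRCh38. *CCL20* (ENSG00000115009) lies on chromosome 2 from 227805739 to 227817564. *CXCL8*, *CXCL1*, *CXCL5*, *CXCL3* and *CXCL2* lie on chromosome 4, starting at 73740506, 73869393, 73995642, 74036589 and 74097035, and *CCL2* lies on chromosome 17 from 34255218 to 34257203. *CXCL1*, *CXCL2* and *CXCL3* are close paralogs, and 5.73%, 9.24% and 3.02% of their 50-base stretches occur in other annotated transcripts, so part of their reads is uncertain. *CXCL3* lost its call without untreated replicate 1 and without any 1 of the cocultured replicates. The call was also lost without a filter on low values and with a replicate block. Adjusted p for *CXCL3* was at most 0.0845 over the alternatives.

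**Figure D2:**
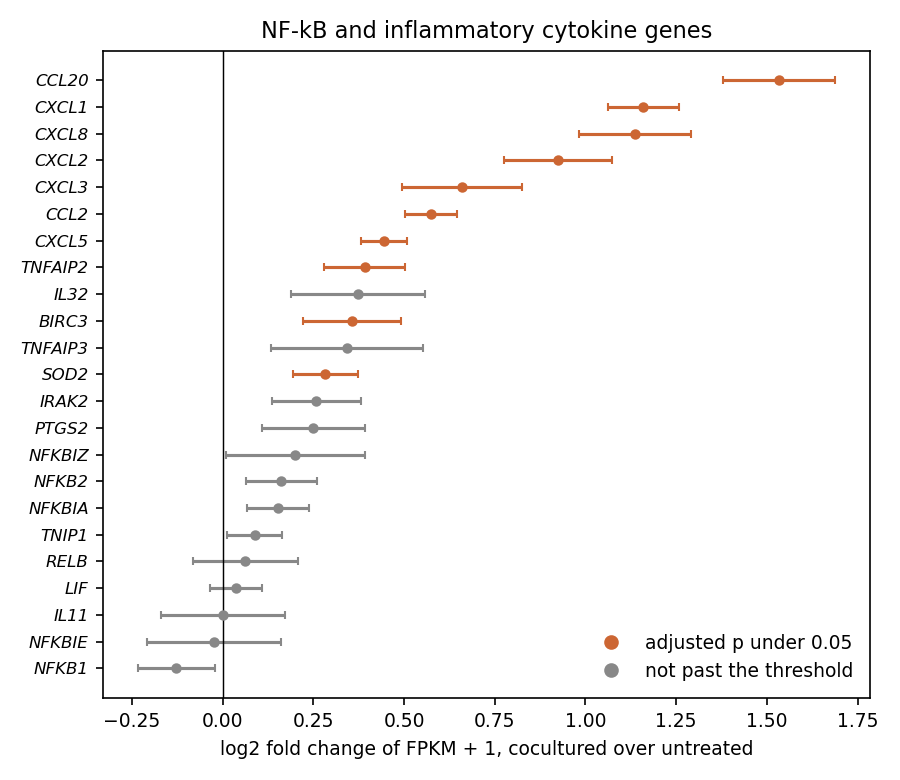
Log2 fold change of FPKM + 1, cocultured over untreated, for the 23 tested NF-kB and inflammatory cytokine genes, with 95% confidence intervals from limma. The 10 genes with adjusted p under 0.05 (orange) are all higher in coculture, up to 1.53 for CCL20, and NFKB1 is the lowest at -0.13.

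Single genes of metal, iron and polyamine handling were among the largest changes, while their lists did not pass camera. *LCN2*, which encodes the siderophore-binding protein lipocalin 2, rose from 1.85 ± 0.335 to 5.43 ± 0.418 FPKM (log2 fold change 1.18 ± 0.096 SE, adjusted p = 0.00562). *TFRC* fell by 0.53 ± 0.021 on the log2 scale (adjusted p = 0.000216). *SAT1*, which acetylates spermidine and spermine, rose from 60.2 ± 0.664 to 94.96 ± 5.36 FPKM (0.65 ± 0.040, adjusted p = 0.00158). *SLC30A1*, a zinc exporter, rose from 9.77 ± 0.523 to 13.98 ± 0.788 FPKM (0.48 ± 0.052, adjusted p = 0.0199). Its call was lost without each library in turn except cocultured replicate 2. The call was also lost without a filter on low values, without an intensity trend and with a replicate block. Adjusted p for *SLC30A1* was at most 0.0988 over the alternatives. In the iron list, with 17 tested members, 1 rose and 1 fell over all genes and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.976), with a median of -0.011 and a mean of 0.038 log2 units. The ferritin genes *FTH1* and *FTL*, chosen after their values were seen, were at 213 and 200.003 and at 2922 and 2813 FPKM (adjusted p = 0.211 and 0.397). In the polyamine and arginine list *AMD1*, which makes the aminopropyl donor, fell by 0.30 (adjusted p = 0.0232), with 5 higher and 4 lower of 17 adjusted over the list alone (camera adjusted p = 0.668). In the metallothionein and metal response list, 1 of 8 rose over all genes, and 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0585, but 0.0138 without a filter on low values and 0.0421 without untreated replicate 2). *TFRC* (chromosome 3, 196027183 to 196082189) overlaps an annotated antisense gene, and *SAT1* lies on chromosome X from 23783173 to 23786226, *LCN2* on chromosome 9 from 128149071 to 128153455.

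Among genes with at least 5 FPKM, others with large falls were *EPAS1*, which encodes the hypoxia-inducible factor HIF-2 alpha, and *CPLX2*, which encodes a regulator of vesicle fusion. *EPAS1* fell from 39.9 ± 0.526 to 31.4 ± 0.598 FPKM (log2 fold change -0.34 ± 0.025 SE, adjusted p = 0.00405) and *CPLX2* from 258 ± 4.69 to 204 ± 6.21 FPKM (-0.34 ± 0.027, adjusted p = 0.00562). *LBH* (-0.42), the basement membrane proteoglycan gene *AGRN* (-0.38), the mucin gene *MUC5B* (31.1 ± 2.05 to 23.7 ± 1.61 FPKM, -0.38), the clock gene *PER2* (-0.35), *DHRS3* (-0.35), *ALDH3B1* (-0.34) and *ZDHHC12* (-0.33) completed the 10 largest falls among changed protein-coding genes with at least 5 FPKM in the higher group and no overlap between groups. By FPKM, the keratin gene *KRT81* fell from 489 ± 2.48 to 423 ± 15.4, the amino acid transporter gene *SLC7A5* from 218 ± 6.26 to 179 ± 6.50 and *TAGLN2* from 185 ± 0.363 to 161 ± 7.66, while *HSP90AA1* rose from 514 ± 13.1 to 584 ± 8.36 and *AKR1B1* from 250 ± 4.90 to 278 ± 5.41. *KRT81* shares 44.6% of its 50-base stretches with other transcripts, mainly *KRT86*, and *HSP90AA1* shares 17.5%, mainly with pseudogenes. Of the 26 genes named by size, 12 were called without untreated replicate 1 and without cocultured replicate 3, and 14 without each of the others, with adjusted p up to 0.159. Without a filter on low values 13 were called, without an intensity trend 14 and with a replicate block 13. *TAGLN2* lost its call after GC correction (-0.16, adjusted p = 0.0635), with pseudocounts of 0.1 (0.0507) and 5 (0.0511) and with median-of-ratios scaling (0.0553), and *AKR1B1* lost its call after rescaling to a common sum (0.0519).

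Besides NF-kB, 3 lists were higher in coculture. The MAPK feedback list had a median log2 fold change of 0.092 over 14 tested genes (camera adjusted p = 0.00177, and adjusted p = 0.524 with an estimated correlation). *EREG*, a ligand of the EGF receptor on chromosome 4 (74365143 to 74388751), rose from 11.5 ± 0.192 to 16.2 ± 0.573 FPKM (0.46 ± 0.034 SE, adjusted p = 0.00405), and was the only member past the threshold over all genes, against 5 higher adjusted over the list alone. The mitosis and proliferation list had a median of 0.076 over 27 genes, 24 of them positive (camera adjusted p = 9.37e-05, and adjusted p = 0.246 with an estimated correlation). *TOP2A*, a DNA topoisomerase, rose from 164 ± 3.69 to 185 ± 5.51 FPKM (0.18, adjusted p = 0.0436), and 9 members were higher adjusted over the list alone. *TOP2A*, the member called over all genes, lost its call with median-of-ratios scaling (0.0514), without a filter on low values (0.142) and without an intensity trend (0.129). The call was also lost with a replicate block and without each library in turn (up to 0.150). The median GC content of this list was 43.2%, and its median was 0.068 after GC correction. The interferon-stimulated list had a median of 0.073 over 15 genes, with none changed over all genes or over the list alone (camera adjusted p = 0.0408, and adjusted p = 0.462 with an estimated correlation). *IFIT1* was at 2.06 and 2.49 FPKM (adjusted p = 0.136) and *OAS1* at 48.7 and 45.9 (adjusted p = 0.137). At an unadjusted p under 0.05, 3 of its members were higher and 1 lower, and limma-voom called none. Of all 12575 tested genes, 2525 had an unadjusted limma p under 0.05. The interferon call was lost with a pseudocount of 5 (0.0508), a mean of at least 5 FPKM (0.4999), quantile normalization (0.0556) or limma-voom (0.0857), and without untreated replicate 3 (0.109), cocultured replicate 2 (0.0841) or cocultured replicate 3 (0.0938).

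A further 4 lists were lower in coculture, each by a small median. Targets of p53 had a median of -0.10 over 28 genes, 24 of them negative (camera adjusted p = 0.000128, and adjusted p = 0.452 with an estimated correlation). *BAX*, a pro-apoptotic gene, fell from 34.0 ± 1.17 to 29.3 ± 0.958 FPKM (-0.21, adjusted p = 0.0498). Its call was lost after GC correction (-0.16, adjusted p = 0.0604), with a pseudocount of 0.1 (0.0507) and after rescaling to a common sum (0.0555). The call was also lost without a filter on low values, without an intensity trend, with a replicate block and without each library in turn. Adjusted p for *BAX* was at most 0.168 over the alternatives. In this list, 9 members were lower and 1 higher adjusted over the list alone. Nuclear genes of oxidative phosphorylation had a median of -0.064 over 33 genes, 29 of them negative, with none changed over all genes or adjusted over the list alone (camera adjusted p = 0.00177, and adjusted p = 0.462 with an estimated correlation). At an unadjusted p under 0.05, 11 were lower and none higher, and limma-voom called 4 lower. Among all 12575 tested genes, 2525 had an unadjusted limma p under 0.05 in either direction, the background for such counts here and below. *ATP5B*, for a subunit of ATP synthase, was at 409 and 386 FPKM (adjusted p = 0.118). Ribosomal protein genes had a median of -0.042 over 32 genes, also with none changed over all genes or over the list alone (camera adjusted p = 0.00978, and adjusted p = 0.719 with an estimated correlation). Again 11 were lower and none higher at an unadjusted p under 0.05, and limma-voom called 8 lower. This call was lost after GC correction (0.0576), after quantile normalization (0.0575), without untreated replicate 1 (0.0942) and without cocultured replicate 3 (0.0885). NRF2 and oxidative stress genes had a median of -0.051 over 28 genes, with none changed over all genes and 5 lower adjusted over the list alone (camera adjusted p = 0.0466, and adjusted p = 0.524 with an estimated correlation). At an unadjusted p under 0.05, 13 were lower and 1 higher, and limma-voom called 10 lower. *OSGIN1* was at 10.3 and 7.73 FPKM (-0.37, adjusted p = 0.054). The NRF2 call was lost with a pseudocount of 0.1 (0.0552), a mean of at least 5 FPKM (0.0718), median-of-ratios scaling (0.0580) or quantile normalization (0.0575), and without untreated replicate 1 (0.162) or 3 (0.109) and without cocultured replicate 1 (0.112) or 3 (0.0885).

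**Figure D3:**
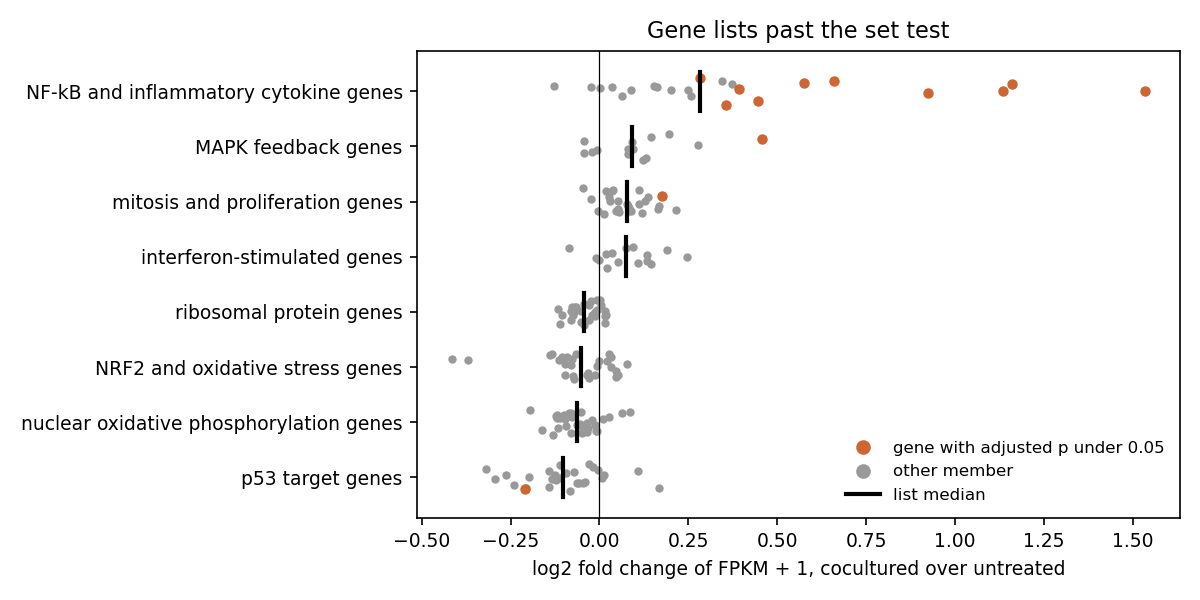
Log2 fold change of FPKM + 1, cocultured over untreated, for each tested member of the 8 lists past camera's threshold, with the list median as a black bar and genes with adjusted p under 0.05 in orange. NF-kB genes spread up to 1.53, whereas the medians of the other 7 lists lie between -0.10 and 0.092.

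Lists of adhesion and differentiation held changed genes and did not pass camera, although 4 of them passed under some alternatives. In the integrin and basement membrane list, 1 of 25 rose and 4 fell over all genes, and 4 were higher and 8 lower adjusted over the list alone (camera adjusted p = 0.0603). This list passed without a filter on low values (0.0208), with limma-voom (0.00426) and without untreated replicate 1 (0.0380). The cell-surface proteoglycan gene *SDC4* rose from 14.7 to 19.2 FPKM (0.36, adjusted p = 0.0102), and the laminin genes *LAMA5* (-0.32, adjusted p = 0.0283) and *LAMB3* (-0.20, adjusted p = 0.0329) fell with *AGRN* and *HSPG2*, the last chosen after its value was seen (-0.24, adjusted p = 0.0436). In the TGF-beta and mesenchymal list, *TGFBI* fell (-0.18, adjusted p = 0.0239) and 1 of 17 was higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0603). It passed without a filter (0.0235), with limma-voom (0.0115) and without untreated replicate 2 (0.0283). *MUC5B* was the changed member among 7 mucin and airway secretory genes over all genes and over the list alone (camera adjusted p = 0.1003), *TAGLN2* among 19 actin cytoskeleton genes by both adjustments (0.335), and *MMP24* (-0.27, adjusted p = 0.0294) among 13 metalloproteinase and plasminogen genes over all genes, with 3 higher and 1 lower over the list alone (0.183). The mucin list passed without a filter (0.00504) and with limma-voom (0.00220), and the actin list with limma-voom (0.0428). None of 22 junction genes changed over all genes, with 1 higher and 1 lower over the list alone (0.699), and none of 18 YAP and TEAD targets, with 1 higher over the list alone (0.976).

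The other stress and metabolic lists did not pass camera, although heat shock (0.0334) and glycolysis genes (0.0454) passed with limma-voom and histone genes without a filter on low values (0.0387). In the hypoxia list, *HIF1A*, which encodes HIF-1 alpha, rose from 104 ± 2.29 to 123 ± 2.97 FPKM (0.25, adjusted p = 0.0187) and the glycolytic regulator *PFKFB3* fell (-0.23, adjusted p = 0.0283), with 1 higher and 2 lower of 21 over the list alone (camera adjusted p = 0.546). *HERPUD1* (-0.20, adjusted p = 0.0294) and *XBP1* (-0.23, adjusted p = 0.0331), genes of the unfolded protein response, fell among 24 tested, with 2 higher and 3 lower over the list alone (camera adjusted p = 0.885). *SLC7A5* was the changed member of 27 amino acid response genes, with 2 higher and 3 lower over the list alone (0.727), and *HSP90AA1* of 19 heat shock genes, with 3 higher over the list alone (0.254). Among 24 immediate early genes *IER3* rose (0.31, adjusted p = 0.0232) and *NR4A3* fell (-0.40, adjusted p = 0.0367), with 4 higher and 4 lower over the list alone (0.885). The anti-apoptotic gene *MCL1* rose (0.16, adjusted p = 0.025) among 23 apoptosis genes in which *BAX* fell, with 2 higher and 2 lower over the list alone (0.456). *ACSS2*, an acetyl-CoA synthetase, rose (0.25, adjusted p = 0.0239) and *SREBF1* fell (-0.24, adjusted p = 0.0444) among 16 fatty acid synthesis genes, with 3 higher and 3 lower over the list alone (0.975). *GPI* fell among 16 glycolysis genes (-0.15, adjusted p = 0.0411), with 1 higher and 1 lower over the list alone (0.325). Of 29 DNA replication genes, 1 was higher and 5 lower adjusted over the list alone (0.325). *GPI* shares 13.7% of its 50-base stretches with other transcripts. *GPI* lost its call after GC correction (-0.12, adjusted p = 0.0620). No member changed over all genes among 25 cholesterol synthesis (2 higher and 3 lower over the list alone, camera adjusted p = 0.727), 28 lysosome and autophagy (none over the list alone, 0.727), 13 mitochondrially encoded (3 higher and 3 lower over the list alone, 0.885), 24 ribosome biogenesis (2 higher over the list alone, 0.640), 11 histone (none over the list alone, 0.361), 11 pattern recognition (1 higher and 1 lower over the list alone, 0.727) or 6 inflammasome genes (none over the list alone, 0.976). Of 19 changed list members that the rule took beyond the 26 largest, 1 was called in each fit without 1 library, with adjusted p up to 0.168. Without a filter on low values 3 of them were called, without an intensity trend 1 and with a replicate block 0.

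Markers of leukocytes and endothelial cells lay below the level for testing in both groups. None of 20 leukocyte markers or 10 endothelial markers reached the level for testing, with highest group means of 0.351 FPKM for *CORO1A* and 0.952 FPKM for *ESAM*. Of 12 fibroblast markers, *FBLN1* (6.97 and 7.01 FPKM) and *LUM* (3.74 and 4.49 FPKM) were tested and neither changed. Of 16 alveolar type 2 genes 4 were tested, too few for camera, and none changed over all genes, with 1 higher and 1 lower adjusted over the list alone and *CEACAM6* highest at 229 and 249 FPKM (adjusted p = 0.054). Expression by GC content differed between libraries along the groups. The Spearman correlation of each library's deviation with GC content was 0.26, 0.39 and 0.027 in untreated replicates 1 to 3, and -0.0000944, -0.22 and -0.44 in cocultured replicates 1 to 3.

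**Figure D4:**
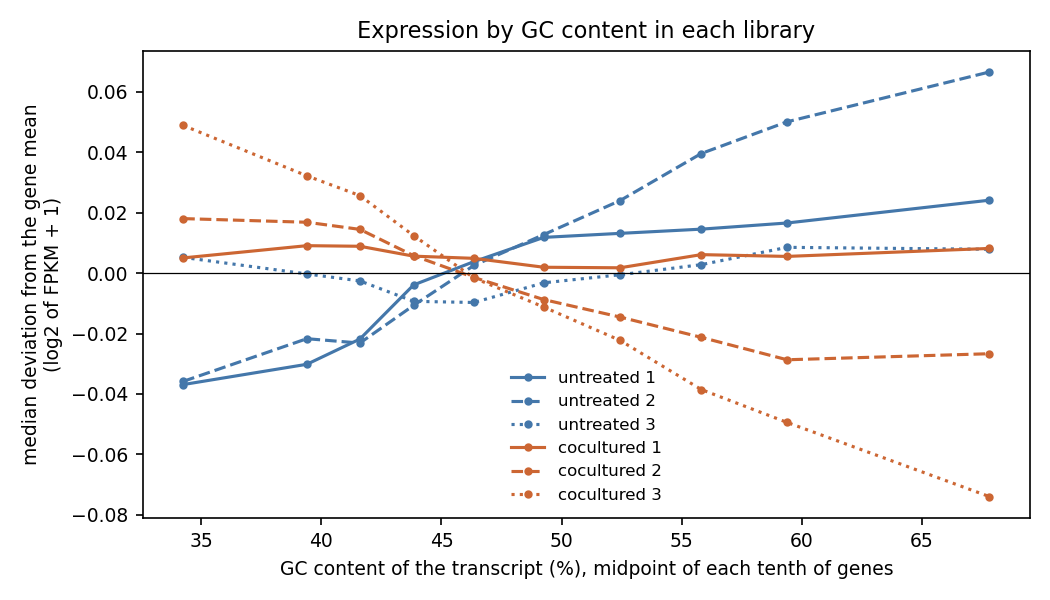
Median deviation of each library from the gene mean, in log2 units of FPKM + 1, for 10 groups of protein-coding genes ordered by transcript GC content in percent, with untreated libraries in blue and cocultured ones in orange. At the highest GC content the medians run from 0.067 in untreated replicate 2 to -0.074 in cocultured replicate 3.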

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

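The GC correction and limma-voom on recovered reads were added after the data were seen, and the other alternatives were fixed before. The count of 170 changed genes was 30 with no filter on low values, 520 among genes with a mean of at least 5 FPKM, 29 without an intensity trend, 1221 with limma-voom on recovered reads and 16 at an adjusted p of 0.01, and leaving out 1 library gave 15 to 26. The filters left 35339 and 6708 genes to test, against 12575, and leaving out 1 library leaves fewer to fit. For the other settings, and for how far these numbers explain the counts, the cause was not tested. The count of 6 genes changed at least 2-fold was 3 with a pseudocount of 5, which compresses fold changes by construction, 9 with a pseudocount of 0.1, 9 after rescaling to a common sum and 20 with limma-voom, and leaving out 1 library gave 4 to 6. The count of 8 lists was 13 with no filter, 5 after quantile normalization, 13 with limma-voom and 0 with an estimated correlation, and 5 to 10 when 1 library was left out. With the estimated correlation, 3 lists had an unadjusted camera p under 0.05. The cause was not tested. Apart from the replicate block, the remaining settings gave 155 to 190 changed genes.

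Replicate numbers did not pair the libraries. Same-numbered libraries had correlations of deviations of -0.040, -0.012 and 0.014, and 0 of 3 libraries in either group correlated best with their own number. With the replicate block, 16 genes and 7 lists passed and the NRF2 call was lost (adjusted p = 0.0644). The design set edgeR's quasi-likelihood test in place of limma only if the table held raw counts. Neither edgeR nor DESeq2 was run, and limma-voom was fitted to the recovered reads.

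All 170 genes kept their sign in each setting that tested them, and 10 were called in all 19 settings. As the groups did not overlap for these 170 genes, many settings could not reverse a sign. These are the settings that left out a library or changed only the pseudocount, filter, variance model or block. Over the 19 settings the NF-kB, MAPK feedback, mitosis, p53 and oxidative phosphorylation lists kept their calls at the preset correlation, whereas the interferon list lost its call in 7, NRF2 in 9 and ribosomal protein genes in 4. These 19 include the main fit. The settings without an intensity trend and with robust empirical Bayes cannot change a camera result, so for lists they repeat the main fit. No named gene past the threshold here or in an alternative changed sign between them. Of 3329 values of named genes and of gene lists over the alternative settings, 2875 kept their side of the threshold, 306 fell below it and 148 passed it. In the simulated libraries 26% of log2 changes of 0.25 were called, against 64% with limma-voom, of whose calls 8.20% were false against 2.10%. How many simulated changes of that size were missed thus depended on the test, and other depths or spreads were not simulated.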

Other observations

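The tests of parasite reads, leukocytes and shared sequence, the count of splits for changed genes and the count of stop codons in genes with iron-responsive elements were chosen after the results were seen, as were the genes named in the next paragraphs.

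Single genes outside the fixed lists also changed, and no group was tested for them. Apart from *EPAS1*, no gene named in this paragraph or the next is among the 12 called whichever library was left out. The untreated mean of *OLR1* lay below the filter of 1 FPKM, so its change is uncertain. *C3*, the central complement component, rose from 10.3 ± 0.156 to 12.5 ± 0.415 FPKM (mean ± SD, n = 3, log2 fold change 0.25, adjusted p = 0.0283). *C15orf48* rose from 2.32 ± 0.233 to 3.87 ± 0.328 FPKM (0.55, adjusted p = 0.0283), *OLR1*, a scavenger receptor gene, from 0.749 ± 0.125 to 1.58 ± 0.132 (0.56, adjusted p = 0.0456), and the protease gene *CTSS* from 2.94 ± 0.240 to 4.02 ± 0.0589 (0.35, adjusted p = 0.0411). *UBE2L6* (0.26, adjusted p = 0.0436) and *GBP3* (0.36, adjusted p = 0.0473), both known as interferon-induced, rose too. *TGFBR1*, a TGF-beta receptor gene, fell from 21.9 ± 0.938 to 17.9 ± 0.119 FPKM (-0.28, adjusted p = 0.025), *PMEPA1* from 37.7 ± 0.184 to 32.0 ± 1.14 (-0.23, adjusted p = 0.0274) and *IGFBP3* from 54.8 ± 1.34 to 45.6 ± 0.202 (-0.26, adjusted p = 0.0111).

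*HIF1A* rose while *EPAS1* fell, and *HIF1A-AS2*, a noncoding gene on the opposite strand of *HIF1A*, fell from 1.77 ± 0.243 to 0.465 ± 0.121 FPKM (-0.92, adjusted p = 0.0244). Reads of these overlapping genes may be mixed, since the use of strand is not given in the sources used here, although *HIF1A* was far more abundant at 104 and 123 FPKM and had a log2 fold change of 0.25 in limma. *FGFBP1* (0.38), *CYP1B1* (0.42) and *PRAME* (0.27) rose.

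The rise of NF-kB genes was set against technical explanations. After GC correction the list's median was 0.28, against 0.28 before. Medians of the 10 groups of genes by GC content ran only from 0.044 to -0.060. The correction could thus hardly have removed the rise, and a trend of that size does not account for it. The 13 of 23 tested members that share no 50-base stretch with another gene had a median of 0.20 (95% bootstrap interval 0.063 to 0.39). Of these, 4 changed over all genes, so shared stretches do not account for the whole rise. This bootstrap interval and the next resample genes, which are not independent replicates, and leave out the spread between libraries. Parasite reads counted on human genes were predicted to raise genes of proteins conserved across eukaryotes, but 39 such genes had a median of 0.015 (95% bootstrap interval -0.014 to 0.032). Whether parasite reads can align to human genes was not tested, so this shows only that these genes did not rise as a set. Leukocytes would bring their abundant transcripts, and the highest marker mean in coculture was 0.351 FPKM. The labels name only a cell line and the parasite, so that outcome was given by the design and decides nothing. A response of the A549 cells to coculture is a candidate explanation that was not tested. The part of paralogous reads in the sizes for *CXCL1*, *CXCL2* and *CXCL3*, and the grouping of few libraries, stay open.

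The small shifts of the growth-related lists were set against the GC trend of the libraries. Medians after correction were 0.068 for mitosis (0.076 before, adjusted p = 0.000314), -0.096 for p53 targets (-0.10 before) and -0.069 for oxidative phosphorylation (-0.064 before). Median GC content was 46.6% for p53 targets and 45.5% for oxidative phosphorylation. Protein-coding genes with such GC content had a median log2 fold change of 0.0012. The correction could thus hardly have removed these falls and is no test of them. A trend of that size and direction does not account for them. Genes with the GC content of the mitosis list (43.2%) had a median of 0.014, which argues against the GC trend as the whole cause of its rise. For ribosomal protein genes the median went from -0.042 to -0.027 and the adjusted p to 0.0576, so the GC trend and coculture cannot be told apart there, as the median kept over 0.5 of its size while the call ended. As a description, the mitosis median lay at the 99.97 percentile of 10000 random lists matched on GC content and expression (95% of which lay between -0.021 and 0.042), and no biological cause was tested for these lists. All these calls were lost with an estimated correlation.

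The fall of *TFRC* was -0.56 after GC correction (95% interval -0.61 to -0.52). *TFRC* has 41.5% GC, and the tenth of protein-coding genes with such GC content had a median log2 fold change of 0.032. The trend there ran toward a rise, so the correction could not have removed the fall and is no test of it. A trend of that direction does not account for the fall. *TFRC* mRNA is stabilised through iron-responsive elements in the 3' untranslated region, and a general loss of mRNAs with such elements may contribute. The other tested genes with such elements had a median log2 fold change of 0.043 (*SLC11A2* -0.032, *CDC42BPA* 0.043, *CDC14A* 0.11, with 95% limits from -0.12 to 0.31), which met the bound set beforehand against it. That bound took no account of isoforms, and a look at the annotation after this result was seen gave 7, 2 and 8 stop codons for these genes, whose summed values can include isoforms without the elements, so the explanation was kept open.

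The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split alone (1 of 10) gave 170 changed genes, against at most 2 in another split. It was also 1 of 10 for genes changed at least 2-fold (6, against at most 2) and 1 of 10 for lists (8, against at most 6). Every other split mixes untreated and cocultured libraries on both sides. A real group difference would then widen the spread within sides and lower the counts, so these counts do not show what unrelated libraries would give.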
